A study of Mus musculus with 4 samples.

How the data were processed

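RNA from bone marrow cells of C57BL/6N mice was measured on 4 Affymetrix GeneChip Mouse Gene ST arrays, 1 array per sample. The mice had received 1 intraperitoneal injection of phosphate-buffered saline (PBS) or of 50 µg lipopolysaccharide (LPS), and marrow was taken 8 h later. The PBS group held replicates 1 and 3 and the LPS group replicates 1 and 2, numbered as in the sample titles. The labels call the samples replicates but do not say whether each came from 1 mouse. The spread between these samples may thus be partly technical and need not be that between mice. In the gene tests, the spread of each gene (2 residual degrees of freedom) was combined with that over all genes (5.59 prior degrees of freedom).

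The deposited values are log2 expression values per probe set, made by the authors with RMA (background correction, quantile normalization and median polish), per the submitters' processing notes. The version of RMA and its probe annotation are not given in the sources used here. The log2 scale was read from the deposited values, which ran from 2.76 to 14.52 with near-equal quantiles in the 4 columns. The table held 35556 probe sets and no missing values. Genes were named through the platform annotation paired with the probe sets: 21789 probe sets had exactly 1 gene symbol, 1621 had several and were not used for named genes, and 12146 had no gene named here. Of the probe sets with 1 symbol, 21698 had an Entrez identifier found in the RefSeq gene table of GRCm38.p6, and 0 symbols needed an update. Where a gene had several probe sets, as 999 did, the probe set with the highest mean over the 4 arrays stood for it, which left 19938 genes. No filter on low values was applied, and no background level per probe set was used. For arrays, the number of samples limits the precision, and the residual degrees of freedom were 2.

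LPS and PBS were compared on the log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with all 4 arrays in 1 fit and no covariate. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all 19938 genes. Adjusted p-values of genes are from this limma fit, and intervals are its 95% intervals. The prior degrees of freedom were 5.59. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

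Before the data were examined, 22 pathway lists and 18 cell type lists of genes were written down, together with the test, the rule for named genes and most of the other settings tried. Each list was tested against all other genes with camera, with the correlation between genes preset at 0.01, and adjusted over the pathway lists or over the cell type lists. With this preset the degrees of freedom of camera come from the number of genes, not of samples. Its p thus allows little for a shift that the genes of a list share in 1 sample. Camera with a correlation estimated from the arrays was run beside the preset version. That version has only the 2 residual degrees of freedom, so a list that failed there was not thereby shown to be correlated. Fry was run as well. Its directional p tests whether the genes of a list move one way on balance without comparing them with other genes. Some genes stood in more than 1 list. The pathway lists covered the angiopoietin and angiopoietin-like family, PPAR targets, hypoxia-inducible factor targets, glucocorticoid targets, interferon-stimulated genes, inflammatory cytokines, chemokines, NF-kappaB genes, acute phase genes, pattern recognition receptors, metallothionein and iron genes, MHC class I and class II presentation, niche growth factors, growth factor receptors, DNA replication, mitosis, apoptosis, antimicrobial effectors, ribosomal proteins, cholesterol and fatty acid synthesis, and stress or immediate-early genes. The cell type lists covered primary and later granule genes of neutrophil precursors, mature neutrophils, monocytes and macrophages, erythroid cells, megakaryocytes, early and mature B cells, plasma cells, T cells, natural killer cells, dendritic cells, eosinophils with basophils and mast cells, stem and progenitor cells, endothelium, mesenchymal stroma, adipocytes and osteoclasts.

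The named genes were Angptl4, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose arrays did not overlap between groups, up to 3 rising and 3 falling members of each list, and every measured member of the angiopoietin family. Clone names, receptor gene segments, olfactory receptors and small RNAs were left out of the largest changes. In a list with no member past the threshold, the 2 members with the highest mean level were named. This gave 116 genes. Of these, 3 had several probe sets, and the probe sets of 0 of them differed in sign by more than 0.5 log2.

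The fit was tested on 20 simulated sets of the 19938 genes in 4 arrays, with 200 genes changed by known amounts. Gene means were those of the real genes. Variances were drawn, without regard to mean level, from the distribution that limma fitted to the real genes. Noise was independent between genes. The simulated data thus met the assumptions of the fit, and the values that follow cannot test those assumptions. It recovered 21.0% of genes changed by 0.5 log2, 95.9% of those changed by 1 log2 and 100% of those changed by 2 log2. False calls made up 4.01% of calls on average. A list shifted by a small known amount, the mitosis genes, was called by camera in 19 of the 20 sets. Its genes were uncorrelated in those sets, whereas on the real arrays their estimated correlation was 0.371.

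The settings tried beside this fit were shifting each array to the same median, quantile normalization, filters at the 30th percentile and the median of mean level, the mean of a gene's probe sets, every probe set in the fit, an intensity trend with robust eBayes, an unmoderated linear model, an adjusted p under 0.01, an estimated correlation, fry, and leaving out each array in turn. With an array left out, 1 group held a single array, which was assumed to vary like the other group. After the data were seen, the median level of the stromal markers and that of the adipocyte markers per array were each added as a covariate.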

Results

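Bone marrow cells of C57BL/6N mice were profiled 8 h after an intraperitoneal injection of PBS (2 arrays) or of 50 µg LPS, the outer membrane glycolipid of Gram-negative bacteria, here a mixture from Escherichia coli and Salmonella minnesota (2 arrays). The study asked which genes change in the marrow under this acute inflammation, with Angptl4 named in its title. The median log2 value over genes lay between 8.01 and 8.03 on each of the 4 arrays. Across genes, which are not independent replicates, the PBS arrays correlated at r = 0.995 and the LPS arrays at 0.997, and arrays of different groups at 0.988 to 0.990.

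Angptl4, which encodes a secreted inhibitor of lipoprotein lipase, was higher after LPS. Its log2 value was 8.32 and 8.65 in PBS replicates 1 and 3 and 9.42 and 9.69 in LPS replicates 1 and 2, so both LPS arrays lay above both PBS arrays. The group means were 8.49 ± 0.23 and 9.56 ± 0.19 (SD, n = 2 each). The log2 fold change was 1.07 (SE 0.138, 95% interval 0.75 to 1.39), a 2.10-fold rise with a limma adjusted p of 0.0052. With all 35556 probe sets in the fit the same change had an adjusted p of 0.0561 and did not pass. Over the other alternatives with a value for Angptl4, the adjusted p ran from 0.000201 to 0.00771. The lowest was with the stromal covariate, where the prior degrees of freedom were 9.90 in place of 5.59. The unmoderated linear model called 0 genes, so Angptl4 did not pass there either. The SE of 0.138 is itself moderated by limma with the spread over all genes. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333.

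Other genes of the angiopoietin system changed in both directions. Angpt2, a ligand of the endothelial receptor Tie2, rose by 0.91 log2 (SE 0.0916, adjusted p = 0.00148). Tek, which encodes Tie2 itself, fell by 0.89 (SE 0.113, adjusted p = 0.00489), its activating ligand Angpt1 fell by 0.65 (SE 0.128, adjusted p = 0.0382) and Angptl1 fell by 0.81 (SE 0.0978, adjusted p = 0.00375). The log2 fold changes of Tie1 (-0.28), Angpt4 (0.08), Angptl7 (0.04) and Angptl6 (-0.02) did not pass. Of the 9 measured members, 2 rose and 3 fell over all genes tested, and 2 rose and 4 fell adjusted over the list alone. The family as a list was not shifted (camera adjusted p = 0.564). Angpt1 did not pass without LPS replicate 1 (adjusted p = 0.0538) or without LPS replicate 2 (adjusted p = 0.0688).

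**Figure D1:**
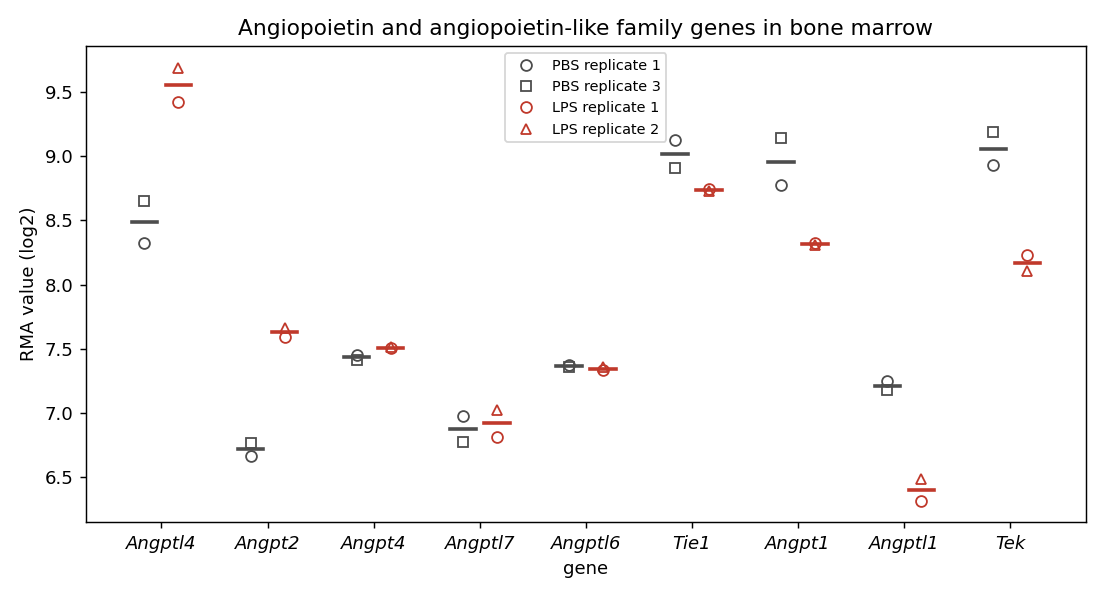
Log2 RMA values of the 9 measured angiopoietin family genes on each array, with PBS in grey and LPS in red and a bar at each group mean. Angptl4 and Angpt2 sit higher on both LPS arrays, and Angpt1, Angptl1 and Tek sit lower.

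Of 19938 genes, 476 rose and 254 fell after LPS, and 65.2% of the 730 changed genes were higher. At least 2-fold changes were mostly rises, with 169 genes up and 26 down. The largest rise was that of Saa3, an acute phase apolipoprotein, at 98.2-fold (log2 6.62, SE 0.135, adjusted p = 1.81e-06). Its PBS mean of 6.65 lay near the lower quartile of genes (6.66 to 6.72 per array), and no background level was used, so the size of this fold is uncertain. The same holds for the other changed genes named here with a group mean under the highest of these quartiles. These are Il6 (5.02 in PBS and 6.48 in LPS), Tnip3, Saa2, Angpt2, Cd163, Abca8a, Angptl1, Il7, Klra8 and, among the families below, Cd209d (6.56 in LPS). Saa3 was followed by the interferon-inducible Ifi205 (4.01 log2), the cytotoxic protease gene Gzmb (3.84), the chemokine genes Cxcl10 (3.76), Ccl2 (3.69), Cxcl9 (3.41) and Cxcl13 (2.97), the protease inhibitor gene Serpina3n (3.47), the complement factor gene Cfb (3.28), the interferon-induced GTPase genes Iigp1 (3.05) and Gbp5 (3.01), and Ly6i (2.94). Their limma adjusted p-values were at most 0.000689, and that of Serpina3n became 0.0832 with an intensity trend and robust eBayes.

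Several of the largest falls were in receptor genes. Cd163, the scavenger receptor for haemoglobin bound to haptoglobin, fell by 2.41 log2 (SE 0.0948, adjusted p = 1.91e-05), from 8.91 to 6.49. The lectin receptor genes Cd209a (-2.02), Clec7a (-1.81) and Mrc1 (-1.72) fell as well, as did Slc40a1 (-1.89), which encodes the iron exporter ferroportin. Fcer2a, the low-affinity IgE receptor of B cells, changed by -1.61 and Ccr3, a chemokine receptor of eosinophils, by -1.59. The remaining large falls were those of the enzyme genes Fmo2 (-2.51), Cmbl (-1.61) and Adh1 (-1.47) and the transporter genes Abca8a (-1.35) and Abca9 (-1.34). Adjusted p-values of these 12 genes were at most 0.00239.

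**Figure D2:**
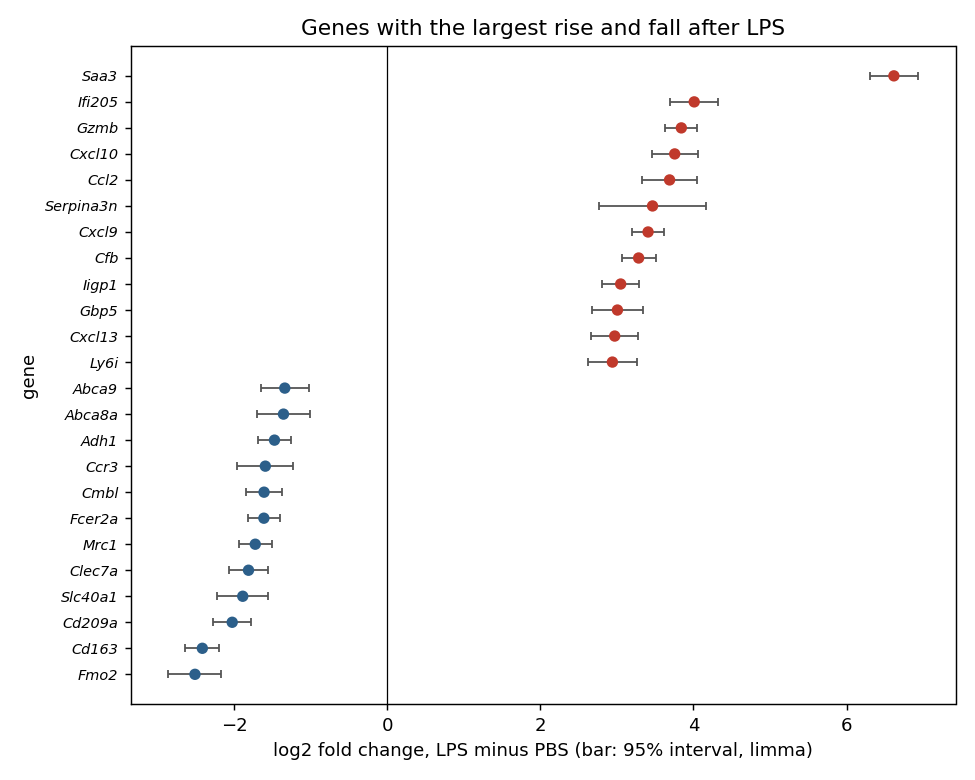
Log2 fold change, LPS minus PBS, of the 12 genes with the largest rise (red) and the 12 with the largest fall (blue), with 95% intervals from limma. Saa3 lies at 6.62, apart from the other rises between 2.94 and 4.01.

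In all 730 changed genes both LPS arrays lay on 1 side of both PBS arrays. Over all genes 44.9% had groups that did not overlap, against 33.3% by chance. The counts rest on the moderated variances: an unmoderated linear model called 0 genes, with 2185 at an unadjusted p under 0.05. The number of lower genes was 382 without PBS replicate 1, 423 without PBS replicate 3, 127 without LPS replicate 2 and 58 at an adjusted p under 0.01, where 286 genes were higher. With every probe set in the fit, named or not, 355 probe sets were higher and 63 lower, so that 84.9% of the changed probe sets were higher. At least 2-fold lower genes numbered 49 without PBS replicate 1.

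Interferon-stimulated genes rose as a block. All 32 measured members rose, both over all genes tested and adjusted over the list alone, with a median log2 fold change of 1.71. Cxcl10, Cxcl9 and Iigp1, given above, changed most, and the list had the lowest camera adjusted p, 1.71e-70 (adjusted p = 0.145 with an estimated correlation). Like every camera p given here with the preset correlation, the first value allows little for differences between samples of a group. MHC class I presentation genes followed, with 12 of 14 up over all genes, 13 adjusted over the list alone and a median of 0.73. Examples were the immunoproteasome subunit gene Psmb10 (1.22), the peptide transporter gene Tap1 (1.10) and Tapbp (0.97). The camera adjusted p was 1.55e-19 (adjusted p = 0.145 with an estimated correlation).

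Chemokine, cytokine and NF-kappaB genes rose as lists. Of 25 chemokine genes, 14 rose and 1 fell, and 15 rose and 1 fell adjusted over the list alone, with a median of 0.97. The member that fell was Ccl6 (-0.86). Camera gave an adjusted p of 2.00e-17 (adjusted p = 0.21 with an estimated correlation). Of 25 cytokines and antagonists, 9 rose, 13 adjusted over the list alone, with a median of 0.28. The largest were Il1rn (2.03), which encodes the interleukin-1 receptor antagonist, Tnfsf10 (1.82) and Il6 (1.46). For this list the camera adjusted p was 7.01e-15 (adjusted p = 0.145 with an estimated correlation). Of 22 NF-kappaB feedback and signalling genes, 13 rose and 1 fell, and 18 rose and 1 fell adjusted over the list alone. The median was 0.55. Tnip3 (2.61), the adhesion molecule gene Icam1 (1.48) and the mitochondrial superoxide dismutase gene Sod2 (1.36) rose and Vcam1 (-0.79) fell. NF-kappaB genes had a camera adjusted p of 1.39e-17 (adjusted p = 0.198 with an estimated correlation).

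Acute phase and STAT3 target genes rose in 9 of 25 cases, 12 adjusted over the list alone, with a median of 0.19. Beside Saa3, they included Steap4 (1.14) and Saa2 (1.05). This list had a camera adjusted p of 2.03e-09 (adjusted p = 0.145 with an estimated correlation). Pattern recognition receptors changed in both directions, with 9 up and 3 down of 24, 13 up and 3 down adjusted over the list alone, and a median of 0.34. The LPS co-receptor gene Cd14 (1.94) and the scavenger receptor genes Msr1 (1.74) and Marco (1.58) rose. Clec7a, given above, Tlr8 (-0.81, and -0.53 without LPS replicate 2) and Clec4d (-0.58) fell. Receptors as a list had a camera adjusted p of 3.63e-06 (adjusted p = 0.145 with an estimated correlation).

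Stress and immediate-early genes, a list that also marks handling of cells, rose in 6 of 19 cases, 7 adjusted over the list alone, with a median of 0.18 (0.08 without LPS replicate 2) and Jun (1.14), Hspa1a (0.96) and Hsph1 (0.86) in front. Stress genes had a camera adjusted p of 1.47e-05 (adjusted p = 0.293 with an estimated correlation). Of 18 apoptosis regulators 1 rose, Casp4 (1.29), a sensor of cytosolic LPS, and 5 adjusted over the list alone, with a median of 0.16. The camera adjusted p was 0.00171 (adjusted p = 0.21 with an estimated correlation). Hypoxia-inducible factor targets held 3 rises among 19, 6 adjusted over the list alone, namely Adm (0.70), Slc2a1 (0.58) and Vegfa (0.43), around a median of 0.03 (0.06 without PBS replicate 1, 0.11 without PBS replicate 3 and 0.08 without LPS replicate 2). The camera adjusted p was 0.0367 (adjusted p = 0.485 with an estimated correlation), and the list did not pass without PBS replicate 1 (0.108) or without LPS replicate 1 (0.244).

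DNA replication and mitosis genes were lower as lists, by small amounts. In each list 0 of 25 members passed, also adjusted over the list alone. The medians were -0.15 for replication and -0.16 for mitosis, and all 25 mitosis genes and 23 of the replication genes had negative values. Pcna had -0.15, Rrm1 -0.15, Mki67 -0.15 and Ccna2 -0.22. The camera adjusted p was 0.000524 for replication (adjusted p = 0.485 with an estimated correlation) and 3.28e-06 for mitosis (adjusted p = 0.452 with an estimated correlation). Without LPS replicate 2 the replication list did not pass (median -0.09, adjusted p = 0.0705), and without PBS replicate 1 its median was also -0.09 (adjusted p = 0.0161). MHC class II genes had a median of -0.22 (-0.09 without LPS replicate 1 and -0.36 without LPS replicate 2), with 1 rise, the protease gene Ctss (0.51), and 1 fall, H2-Ob (-0.74), among 9, the same counts adjusted over the list alone. The camera adjusted p was 0.0225 (adjusted p = 0.629 with an estimated correlation), and it was 0.449 without LPS replicate 1 and 0.0585 without PBS replicate 3. B-cell markers moved with this list: as the median deviation from each gene's mean over the 4 arrays, class II genes stood at -0.26 in LPS replicate 1 and 0.04 in LPS replicate 2 and mature B-cell markers at -0.31 and 0.07, and H2-Ob is a member of both lists.

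The other pathway lists were not shifted by camera. PPAR targets had a median of -0.07 and a mean of 0.05, with 1 rise, the lipid droplet gene Plin2 (0.75), among 16, against 3 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.835). Glucocorticoid targets, with a median of -0.03 and a mean of 0.05, held 4 rises and 1 fall among 15, and 5 and 2 adjusted over the list alone (camera adjusted p = 0.51). Il1r2 (1.20) and the metallothionein genes Mt1 (0.83) and Mt2 (1.26) were among the rises. Metallothionein, iron and heme genes had a median of 0.00, with 3 rises, among them the zinc and iron importer gene Slc39a14 (0.99), and 1 fall among 15, and 3 and 4 adjusted over the list alone (camera adjusted p = 0.842). Niche growth factors had a median of 0.05, a mean of -0.07 and a downward test. Csf1 (0.69) rose and 4 of 21 fell, among them Igf1 (-0.82) and the lymphoid growth factor gene Il7 (-0.65), with 1 rise and 5 falls adjusted over the list alone (camera adjusted p = 0.842).

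Of 23 growth factor receptors 3 rose, Csf2rb2 (0.69), Csf2rb (0.52) and Tnfrsf1b (0.52), and 4 rose and 4 fell adjusted over the list alone, with a median of -0.04 (camera adjusted p = 0.842). Antimicrobial effectors had a median of -0.11 and a mean of 0.18. Acod1 (2.65), the enzyme that makes itaconate, Sod2 and the inducible nitric oxide synthase gene Nos2 (1.05) rose and Lyz2 (-0.44) fell among 17, against 3 rises and 5 falls adjusted over the list alone (camera adjusted p = 0.93). Ribosomal protein genes had a median of -0.01, with 0 of 20 past the threshold on either adjustment, including those adjusted over the list alone (camera adjusted p = 0.996), and Rps6 had 0.00 and Rpl19 -0.01. Cholesterol and fatty acid synthesis genes had a median of -0.08 (-0.045 without LPS replicate 2 and -0.10 without PBS replicate 1). They held 1 fall, Scd2 (-0.55), among 21, also 1 adjusted over the list alone (camera adjusted p = 0.0954). Fry called this list (adjusted p = 0.0177) and 7 of the 13 pathway lists that camera called. Of the 8 lists from PPAR targets to here, all but the cholesterol and fatty acid list had a median that changed sign when 1 array was left out, with no call by camera.

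**Figure D3:**
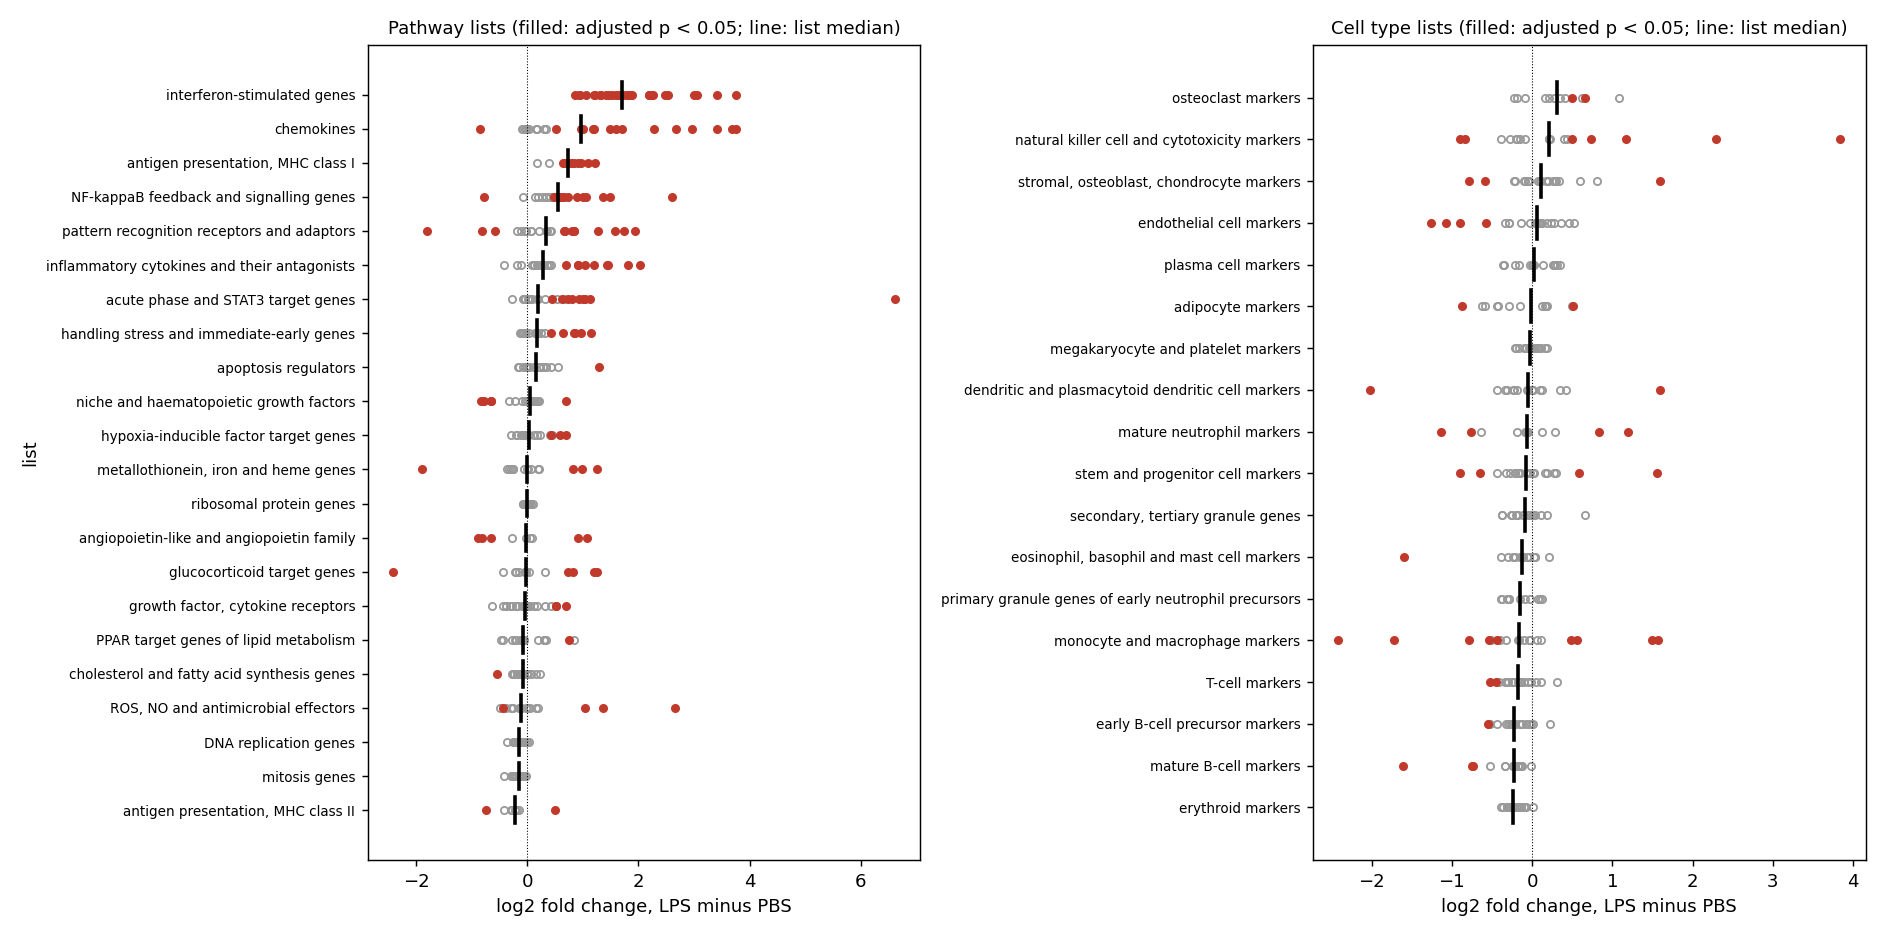
Log2 fold change, LPS minus PBS, of every measured member of the 22 pathway lists (left) and 18 cell type lists (right), with filled points for genes past an adjusted p of 0.05 and a line at each list's median. Interferon-stimulated genes lie wholly to the right of 0, with a median of 1.71, and erythroid markers have the lowest median of the cell type lists, -0.24.

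By camera, 6 of the 18 cell type lists were shifted: mature B-cell, early B-cell, T-cell and erythroid markers lower, and natural killer and osteoclast markers higher (adjusted p = 0.863 with an estimated correlation for each of the 6). Mature B-cell markers fell in 3 of 16 cases, 5 adjusted over the list alone, with a median of -0.23 (-0.05 without LPS replicate 1 and -0.42 without LPS replicate 2), and Fcer2a, given above, Cr2 (-0.75), a complement receptor gene, and H2-Ob changed most. Early B-cell precursor markers had a median of -0.22 (-0.026 without LPS replicate 1 and -0.36 without LPS replicate 2) and 1 fall among 20, Dntt (-0.55), against 5 adjusted over the list alone. T-cell markers had a median of -0.18 and 2 falls among 19, Cd8b1 (-0.52) and Icos (-0.45), also 2 adjusted over the list alone. Erythroid markers had a median of -0.24 (-0.10 without PBS replicate 1, camera adjusted p = 0.0275) with 0 of 19 past the threshold, also adjusted over the list alone, and Car2 had -0.09 and Slc4a1 -0.18. Camera gave adjusted p-values of 3.17e-05 for mature B cells, 0.000525 for early B cells, 0.00686 for T cells and 5.42e-05 for erythroid cells.

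Natural killer and cytotoxicity markers had a median of 0.21 (0.08 without LPS replicate 1 and 0.12 without PBS replicate 3). The effector genes Gzmb, Ccl5 (2.29) and Gzma (1.17) were among 5 rises, the receptor genes Klrd1 (-0.89) and Klra8 (-0.83) were the 2 falls among 18, and 7 rose and 4 fell adjusted over the list alone. Osteoclast markers had a median of 0.31 (0.11 without PBS replicate 1) and 2 rises among 12, Tnfrsf11a (0.66), the receptor of the osteoclast differentiation factor RANKL, and Dcstamp (0.50), against 4 adjusted over the list alone. Camera gave adjusted p = 0.0295 for natural killer and 0.00874 for osteoclast markers (adjusted p = 0.863 with an estimated correlation for both). The natural killer list did not pass without LPS replicate 1 (adjusted p = 0.103), nor the osteoclast list without PBS replicate 1 (0.0557). Fry called 0 of the 18 cell type lists. Among fry's unadjusted directional p-values for the 6 lists that camera called, the lowest was 0.0223, for natural killer markers.

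Neutrophil lists did not pass camera with all 4 arrays. Primary granule genes had a median of -0.15 (-0.014 without LPS replicate 2, adjusted p = 0.689, and -0.28 without LPS replicate 1) with 0 of 11 past the threshold and 1 fall adjusted over the list alone (camera adjusted p = 0.0642), and Srgn had -0.02 and Elane -0.28. Their list was lower by camera without PBS replicate 1 (median -0.23, adjusted p = 0.0275) and without LPS replicate 1 (0.00369), and so was the later granule list without LPS replicate 1 (0.0242). Later granule genes had a median of -0.08 (0.0035 without LPS replicate 2, -0.15 without PBS replicate 3 and -0.17 without LPS replicate 1) with 0 of 16 past the threshold, and 1 rise and 2 falls adjusted over the list alone (camera adjusted p = 0.256), and Lcn2 had 0.01 and Ngp 0.00. Whether the signal is compressed near the highest value of 14.52 was not tested, so the values near 0 of the bright genes Srgn, Lcn2 and Ngp, like those of Rps6, Rpl19 and Ppbp, do not bear on whether a list was shifted. Mature neutrophil markers had a median of -0.07 (0.026 without PBS replicate 1 and -0.17 without LPS replicate 1). Il1r2 and Clec4e (0.84) rose and Ly6g (-1.14) and Retnlg (-0.76) fell among 13, against 2 rises and 3 falls adjusted over the list alone (camera adjusted p = 0.683). Monocyte and macrophage markers split, with 4 rises and 5 falls among 20 and a median of -0.17 (-0.07 without LPS replicate 2 and -0.27 without LPS replicate 1). The high-affinity IgG receptor gene Fcgr1 (1.57), Spic (1.49), a transcription factor gene of iron-recycling macrophages, and Adgre1 (0.56) rose, while Cd163, Mrc1 and Vcam1 fell, and 4 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.0642, and 0.0373 without PBS replicate 1 and 0.00456 without LPS replicate 1). With the level of stromal or of adipocyte markers as a covariate, camera called 9 cell type lists, the 6 above and, as lower, primary granule (adjusted p = 0.042 and 0.00814), monocyte and macrophage (0.0421 and 0.00915) and eosinophil, basophil and mast cell markers (0.0127 and 0.0017).

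Megakaryocyte and platelet markers had a median of -0.02 with 0 of 17 past the threshold, also adjusted over the list alone (camera adjusted p = 0.999), and Ppbp had -0.02 and Pf4 0.04. Plasma cell markers had a median of 0.02 (0.06 without PBS replicate 1, 0.07 without PBS replicate 3, 0.145 without LPS replicate 1 and 0.06 without LPS replicate 2). Of these markers 0 of 14 passed the threshold, also adjusted over the list alone (camera adjusted p = 0.361), and Xbp1 had 0.29 and Edem1 0.03. Dendritic cell markers held 1 rise, Bst2 (1.60), which interferon also induces, and 1 fall, Cd209a, among 17 around a median of -0.05, with 2 and 3 adjusted over the list alone (camera adjusted p = 0.519). Eosinophil, basophil and mast cell markers had a median of -0.13 (0.03 without LPS replicate 2, 0.0024 without PBS replicate 3, -0.24 without PBS replicate 1 and -0.30 without LPS replicate 1) and 1 fall among 18, Ccr3, also 1 adjusted over the list alone (camera adjusted p = 0.0729, and 0.00308 without PBS replicate 1, 0.00019 without LPS replicate 1, 0.411 without PBS replicate 3 and 0.922 without LPS replicate 2). Stem and progenitor markers had a median of -0.07 (-0.019 without LPS replicate 2, -0.13 without LPS replicate 1 and -0.13 without PBS replicate 3). Procr (1.55) and Egfl7 (0.59) were up and Tek and Angpt1 down among 22, against 2 rises and 3 falls adjusted over the list alone (camera adjusted p = 0.576). Platelet, dendritic and, below, endothelial medians changed sign when 1 array was left out, with no call by camera.

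Endothelial markers had a median of 0.06, a mean of -0.11 and a downward test. The falls, 4 among 21, included Stab2 (-1.26), a scavenger receptor gene of sinusoidal endothelium, the adhesion molecule gene Sele (-1.07) and Tek, and 4 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.683). Mesenchymal stromal, osteoblast and chondrocyte markers had a median of 0.11. The collagenase gene Mmp13 (1.60) rose and Vcam1 and the leptin receptor gene Lepr (-0.59) fell among 22, also 1 and 2 adjusted over the list alone (camera adjusted p = 0.683). Adipocyte markers had a median of -0.01, with Dgat2 (0.52) up and Pparg (-0.87) down among 14, against 1 rise and 2 falls adjusted over the list alone (camera adjusted p = 0.683).

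The samples of 1 group differed in cell type markers. As the median deviation from each gene's mean over the 4 arrays, stromal markers stood at -0.40 in PBS replicate 1 and 0.30 in PBS replicate 3, against 0.07 in both LPS arrays. Adipocyte markers stood at -0.44 in LPS replicate 1 and 0.20 in LPS replicate 2, against 0.01 and 0.12 in the PBS arrays. With PBS replicate 1 left out the stromal list was lower by camera (median -0.18, adjusted p = 0.00098), and with PBS replicate 3 left out it was higher (0.47, adjusted p = 2.72e-07). The adipocyte list was higher without LPS replicate 1 (0.27, adjusted p = 0.0242) and lower without LPS replicate 2 (-0.52, adjusted p = 5.2e-05). Mature B-cell markers stood at -0.31 in LPS replicate 1 and 0.07 in LPS replicate 2, and early B-cell markers at -0.23 and 0.04, and LPS replicate 2 lay below both PBS arrays in both lists. Without LPS replicate 1 the mature B-cell list still passed camera (median -0.05, adjusted p = 0.0242), and the early B-cell list did not (median -0.026, adjusted p = 0.0674). Between PBS replicates 74 genes differed by more than 2-fold, and between LPS replicates 9 did.

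Of the 95 named genes past the threshold besides Angptl4, 20 did not pass when 1 array was left out. Without LPS replicate 1 these were 13 genes (Angpt1, Slc2a1, Vegfa, Ctss, H2-Ob, Csf2rb, Lyz2, Scd2, Adgre1, Icos, Egfl7, Lepr and Dgat2, adjusted p from 0.0501 to 0.253), and without LPS replicate 2 they were 14 (Angpt1, Vegfa, Tlr8, Clec4d, Ctss, Il7, Tnfrsf1b, Lyz2, Scd2, Dntt, Cd8b1, Icos, Dgat2 and Dcstamp, from 0.051 to 0.243). Without PBS replicate 1 Vegfa, Lyz2, Adgre1 and Icos did not pass (from 0.055 to 0.0992), and without PBS replicate 3 Vegfa, Il7, Cd8b1 and Dgat2 did not (from 0.0579 to 0.0682). With every probe set in the fit, 32 of these 95 genes did not pass.

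**Figure D4:**
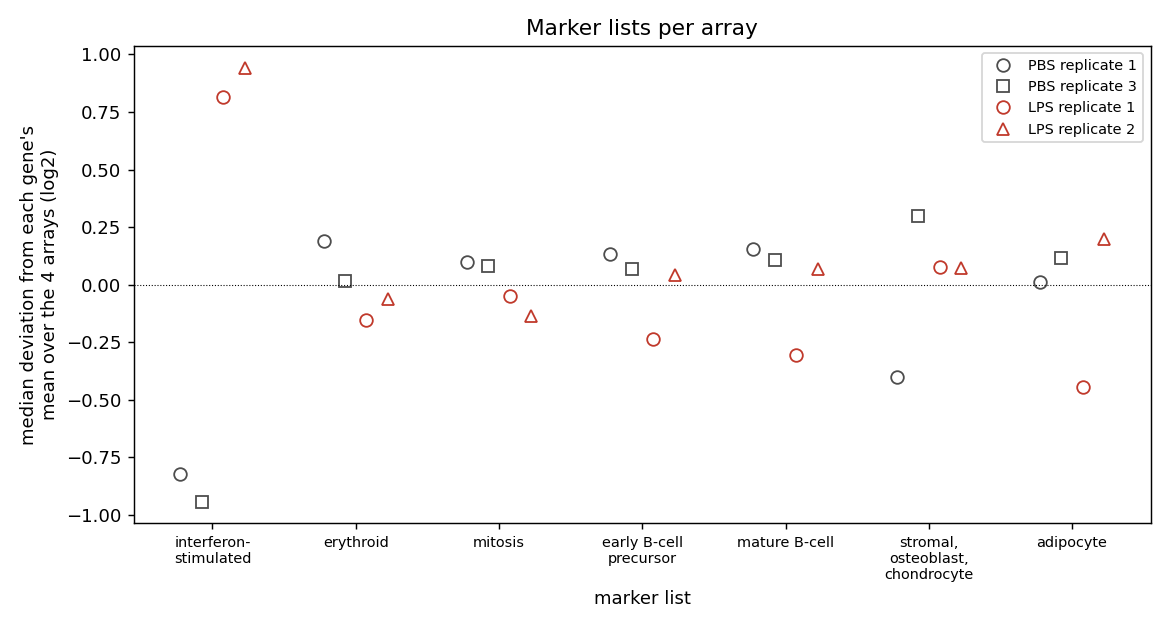
Median deviation of 7 marker lists from each gene's mean over the 4 arrays (log2), with 1 point per array, PBS in grey and LPS in red. Interferon-stimulated genes separate the groups, from -0.94 and -0.82 to 0.81 and 0.94, while stromal markers spread between the PBS arrays and adipocyte markers between the LPS arrays.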

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

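No paired analysis was possible because the groups share only 1 replicate number. The alternatives were planned before the data were examined, except the stromal and adipocyte marker covariates, which were chosen after seeing the data. Besides Angptl4, 95 named genes passed the threshold. Of these, 62 stayed past it under every alternative that tested them at the 0.05 threshold with moderation. The direction changed in 0 of the 95, but with 1 array left out this was fixed, since their groups did not overlap. It was also fixed in settings that kept the fold changes. Of the 19 lists that camera called, 0 kept their call under every alternative, because with an estimated correlation camera called 0 pathway lists and 0 cell type lists, and fry called 8 and 0. Camera with an estimated correlation has only the 2 residual degrees of freedom, so a list could fail there whatever its correlation. The cytokine, acute phase and pattern recognition receptor lists had estimated correlations of -0.024, -0.032 and -0.037. Each still had a camera adjusted p of 0.145 there. Losing a call in that setting is thus not by itself evidence of correlation between genes. Apoptosis regulators and osteoclast markers also had estimates below 0 (-0.012 and -0.0067). The other called lists had estimates above the preset of 0.01, from 0.0729 for T-cell markers to 0.857 for erythroid markers. For lists correlated above the preset, camera p-values with the preset may be too low. Counts over the arrays left out in turn ran from 385 to 696 genes higher, from 127 to 423 lower and from 24 to 49 at least 2-fold lower, and Angptl4 from 0.91 to 1.23 log2, past the threshold each time. Lower genes numbered 382 without PBS replicate 1, 423 without PBS replicate 3 and 127 without LPS replicate 2, where the lone sample of a group was assumed to vary like the other group. At least 2-fold lower genes numbered 49 without PBS replicate 1. The median of the stromal markers ran from -0.18 without PBS replicate 1 to 0.47 without PBS replicate 3, and that of the adipocyte markers from -0.52 without LPS replicate 2 to 0.27 without LPS replicate 1. With only genes above the median level, 16 genes were at least 2-fold lower and 3 cell type lists were called, from fewer genes and list members. With every probe set in the fit, 355 probe sets were higher and 63 lower, of which 45 had exactly 1 gene symbol, and Angptl4, at the same 1.07 log2, had an adjusted p of 0.0561. More tests were made there and the prior degrees of freedom were 3.35 in place of 5.59. Without moderation 0 genes were higher, 0 lower, 0 at least 2-fold higher and 0 at least 2-fold lower, with 2 degrees of freedom per gene. At an adjusted p under 0.01, 286 were higher and 58 lower. With the stromal covariate 561 genes were lower, all 730 genes kept their call and 1222 passed. The prior degrees of freedom were 9.90 there and 11.1 with the adipocyte covariate, against 5.59 in the main fit. With 1 array left out they were 9.92 or 10.9. All these fits leaned more on the spread over all genes, so added calls and lower p-values there do not by themselves show robustness. Camera called 9 cell type lists with either covariate, and with the adipocyte covariate the hypoxia (adjusted p = 0.108) and MHC class II (0.098) lists did not pass. Causes were not tested beyond these constructions. No signal over background was used, so which dim genes could not change measurably stays unknown.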

Other observations

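Further gene families, picked after their values were seen, held groups of changed members, and the two-sided Fisher's exact tests of their share of changed genes against all genes, adjusted over these 12 families, only describe that choice. Of 8 guanylate-binding protein genes, which encode interferon-induced GTPases acting on intracellular pathogens, 7 rose, led by Gbp5 (3.01) and Gbp4 (2.49) (adjusted p = 7.97e-09). Of 10 genes of the p200 family, some of which encode DNA sensors, 6 rose, among them Ifi205 (4.01) and Ifi213 (2.16) (adjusted p = 2.62e-06). Of 11 PARP genes 6 rose, among them Parp12 (1.83) and Parp14 (1.53) (adjusted p = 3.73e-06), and all 3 Phf11 genes rose, with Phf11d at 2.71 (adjusted p = 9.78e-05). Of 7 Schlafen genes 4 rose, led by Slfn5 (1.42) (adjusted p = 9.79e-05), and of 19 Ms4a genes 6 rose, led by Ms4a6d (2.91) (adjusted p = 9.78e-05).

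Complement genes held 5 rises among 16, with Cfb at 3.28 and the C3a receptor gene C3ar1 at 1.31 (adjusted p = 0.00027). Coagulation genes moved both ways, with 3 rises and 3 falls among 18 (adjusted p = 9.01e-05). The rises were those of Procr (1.55), which encodes the endothelial protein C receptor, F10 (0.56) and F2r (0.43). The falls were those of Thbd (-1.21), Tfpi (-0.87) and Serpinb2 (-0.59). Among 17 lipase and lipoprotein handling genes, the endothelial lipase gene Lipg rose by 2.49 and Angptl4 by 1.07, the lysosomal lipase gene Lipa changed by -0.78, and the lipoprotein lipase gene Lpl had -0.06 and did not pass (adjusted p of the family 0.0271). The Cd300 receptor family held 1 rise and 3 falls among 8 (adjusted p = 0.000166), with Cd300ld at -0.89. The Cd209 receptor family held 2 falls among 7 (adjusted p = 0.0271), with Cd209d at -1.14. The other members of both families did not pass. Of 34 bitter taste receptor genes 2 fell, Tas2r143 (-0.88) and Tas2r135 (-0.86) (adjusted p = 0.355). Tlr4, which encodes the LPS receptor, had -0.01 and Il1b -0.42, and neither passed, both named after their values were seen. Slc15a2, a peptide transporter gene, differed within both groups, at 8.51 and 6.88 in PBS replicates 1 and 3 and at 8.98 and 6.86 in LPS replicates 1 and 2. With every probe set in the fit, 65 probe sets with no gene named here were higher and 16 lower after LPS, as were 21 and 2 of those with several gene symbols.

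In the following, the tests of cell content, of PPAR targets and with fry were chosen after the result was seen, as was leaving out arrays in the test against random lists, and that test with all arrays was written down before. The rise of Angptl4 by 1.07 log2 could reflect cells of another type in the LPS samples. The 14 adipocyte markers had a median of -0.013 with an SD of 0.435 and the 22 mesenchymal stromal markers a median of 0.11 with an SD of 0.476, which argues against more of either cell type as the whole source. With the level of these markers as a covariate, Angptl4 stood at 1.16 for adipocytes and 1.01 for stroma, past the threshold in both fits. The markers differed little between the groups, so the covariates could remove little of a group difference. These fits are therefore not evidence separate from the marker medians, and they left fewer residual degrees of freedom than the main fit. The prior degrees of freedom in those fits were 11.1 and 9.90, against 5.59 in the main fit. A shared rise of PPAR targets cannot be told apart from a rise of Angptl4 without them, as the list moved both ways (camera adjusted p = 0.835). Which cells of the marrow carried the higher Angptl4 signal was not tested.

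The falls of Cd163 (-2.41) and Mrc1 (-1.72) could reflect fewer macrophages. The other 18 monocyte and macrophage markers had a median of -0.13 with an SD of 0.639, which argues against a loss of all these cells as the whole cause. Whether a subset that carries Cd163 and Mrc1 left the marrow or its cells lowered these genes was not tested, since no list of such a subset was fixed. The lists do not measure cells, and markers that rose, such as Fcgr1 (1.57), widen the spread and can raise the median. As the list mixes monocyte and macrophage markers, a loss of macrophages alone was not tested.

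Erythroid, DNA replication and mitosis markers had medians of -0.24, -0.15 and -0.16, which may come from an offset of the normalization at their signal level. With all arrays these lay at the 0.01, 0.61 and 0.21 percentile of 10000 random lists matched on mean level. The random lists themselves had medians of -0.042, -0.044 and -0.043, so a small offset was present at these levels. They were drawn gene by gene, while the mitosis genes had an estimated correlation of 0.371, so percentiles may be too low. With any 1 array left out the mitosis median lay at most at the 0.31 percentile. This argues against such an offset as the whole of the mitosis shift only so far as its genes vary independently. The sets with 1 array left out share arrays, so they are not separate checks. For the other lists an offset stays open, because the erythroid median lay at the 6.79 percentile without PBS replicate 1 and the replication median at 10.3 without PBS replicate 1 and 7.08 without LPS replicate 2. Differences in cell content between samples of a group cannot be told apart from an effect of LPS with 2 arrays per group, and the lowest fry adjusted p of the 3 lists was 0.0845, for mitosis. The median difference between replicates (PBS replicate 3 minus 1, then LPS replicate 2 minus 1) was -0.17 and 0.07 for erythroid, -0.05 and -0.08 for replication and -0.013 and -0.07 for mitosis markers. Each was smaller in size than the shift between the group means. By median deviation from each gene's mean, erythroid markers stood at 0.017 in PBS replicate 3 and -0.064 in LPS replicate 2. Replication genes stood at 0.038 in PBS replicate 3 and -0.026 in LPS replicate 1. In these 2 lists, though not in mitosis, such nearest arrays of the 2 groups lay closer than the replicates of either group.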
